A study of Mus musculus with 12 samples.

How the data were processed

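RNA from isolated AEC2 of 12 mouse samples was sequenced, and 1 file per library was analysed, each with 1 column of values for the same 16080 Ensembl genes. Per the labels, Dispase was instilled into perfused lungs, the tissue was dissociated mechanically with DNase I, mesenchymal cells were removed by adherence to plastic and CD45-positive cells by magnetic beads, and total RNA went into standard Illumina libraries. The submitters' processing notes name STAR, limma and the mm10 genome without versions; the counting tool, the annotation and the strand setting are not given in the sources used here. Groups were taken from the genotype field of the labels (WT, C185Gneo and C185G, 4 libraries each).

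The deposited values are on a log2 scale. From the values, the authors added 0.5 to each whole read count, multiplied by 1 factor per library and took the log2. Genes with next to no counts are missing from the files used here, and so are all 13 mitochondrially encoded mRNAs. Why the latter are missing is not given. Total counts and shares of counts therefore cover the measured genes only. The whole counts were recovered from the spacing of the values, and 100% of them came out whole within a tolerance of 1e-06 (largest distance 4.8e-09). The count branch of the planned design was therefore not used: the unit is log2, and limma was the test for it. Recovered totals were 15659512 to 23444287 counts per library. The authors' scaling left totals that differ by at most 1.084 times between libraries. Normalized CPM are counts on that scaling divided by the mean scaled total of the 12 libraries and brought to the CPM scale. Median log2 changes over all genes were at most 0.004 on this scaling, so every change is relative to the bulk of the transcriptome, and a shift of all transcripts together would not be seen. Low counts widen the error of fold changes, and the added 0.5 understates the change of genes with few counts.

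Gene symbols and coordinates came from the GENCODE mouse annotation, release 21 (GRCm38), which named 16017 of the Ensembl identifiers and left 63 without a symbol. Genes that share sequence with near-identical copies are called uncertain, because how reads were assigned among them is not given. Antisense and overlapping genes are uncertain for the same reason.

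All 12 libraries entered 1 fit in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with trend and robust), with 1 coefficient per genotype and no covariates. Contrasts were C185G against WT, C185G against C185Gneo and C185Gneo against WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every gene was kept. Data handling used data.table (version 1.17.8) and jsonlite 2.0.0, and figures with Python 3.11.15 and matplotlib 3.10.9.

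Before the data were examined, 35 gene lists were fixed, covering surfactant and lipid genes, ER stress branches, protein degradation, metabolism, cytokines, matrix, p53, interferon, cell cycle, oxidative and heat stress, and markers of other lung and blood cells. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 32 lists tested; camera with an estimated correlation and fry were read beside it. With the preset correlation 15, 19 and 16 lists were called in the contrasts as listed, and with the estimated correlation 0, 0 and 0. Erythrocyte genes (0 of 8 measured), mitochondrially encoded mRNAs (0 of 13) and the sex-linked genes (2 of 6) were not tested. Immune lists were measured in part: 14 of 23 macrophage, 12 of 16 neutrophil and monocyte and 6 of 21 lymphocyte markers.

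The rule for named genes was also fixed before the data were examined. Sftpc, Hspa5, Xbp1, Ddit3, Krt8 and Cdkn1a were always named. From genes with adjusted p under 0.05, a mean of at least 5 CPM and groups that did not overlap, the 8 largest changes in each direction were named for the C185G contrasts and the 5 largest for C185Gneo against WT. Up to 4 members per list, those with the smallest p, were named as examples, and list members against the common direction were added. Predicted genes and pseudogenes were counted and not named. Some genes that the rule selects are not reported here.

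The calls shared by both C185G contrasts were set beside simulated unchanged groups and independent lists, because both contrasts use the same C185G libraries. Alternatives fixed before the data were examined were limma without the mean-variance trend, quantile normalization, a minimum mean of 5 CPM, only the 8 libraries compared, the replicate number as a block, library quality weights, an estimated correlation, fry, and each library left out in turn. Alternatives added after the data were seen were library totals and median-of-ratios scaling, voom weights on the recovered counts, removal of trends with transcript length and GC content, an exact permutation test of list means, medians of called lists without each library, and families of genes formed by symbol.

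The code was tested on data simulated from the real means and library sizes with 200 changed genes. For C185G against WT it recovered 58.2, 73.1 and 92.4% of genes changed by 0.5, 1 and 2 on the log2 scale, for C185G against C185Gneo 55.2, 77.6 and 98.5%, and for C185Gneo against WT 61.2, 80.6 and 95.5%. Of the unchanged genes, 15849, 15850 and 15849 in the contrasts as listed, it called 0.11, 0.057 and 0.057%. A proteasome list raised by 1 was called in each contrast, with 0 of 31 other lists. The simulated genes varied independently of each other and few were changed. These figures therefore check the code and do not show how often lists are called falsely where genes are correlated.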

Results

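Alveolar type 2 epithelial cells (AEC2), the lung cells that make, store and secrete surfactant, were isolated from female Bl6 mice at postnatal day 56 and their RNA was sequenced. The mice carried 1 of 3 genotypes at Sftpc, the gene of surfactant protein C (SP-C), whose precursor contains a BRICHOS domain that assists its folding in the endoplasmic reticulum (ER). The groups were WT, C185Gneo, which the series describes as a hypomorphic control, and C185G, the mutant, with 4 libraries each. Libraries follow the genotype field. The titles of the libraries with genotype C185Gneo carry the name C185G, and those with genotype C185G carry another code, so that read by title the groups could be exchanged. The level of Sftpc was lowest in the libraries with genotype C185Gneo, the group called hypomorphic. Per the labels, tamoxifen was injected intraperitoneally at 200 mg per kg on 2 days and cells were collected on day 7. The comparisons ask how AEC2 transcription changes once mutant SP-C is expressed, with both control genotypes as the reference. Total counts ran from 15659512 in C185G replicate 4 to 23444287 in C185Gneo replicate 1, and 1 read was worth 0.0639 CPM (a count scaled to the library's total) in the shallowest library. WT libraries held 16328539 to 18234353 counts. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Levels are normalized CPM, as mean ± SD with n = 4 per group, and fold changes are on the log2 scale with Benjamini-Hochberg adjusted p-values from 1 limma fit of all 12 libraries.

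Sftpc, the edited gene, was highest in WT, lowest in C185Gneo and intermediate in C185G, with no overlap between the libraries of any pair of groups. Its level was 7464 ± 194 normalized CPM in WT, 895 ± 143 in C185Gneo and 2832 ± 256 in C185G (SD, n = 4 each). Sftpc therefore fell by 1.40 in C185G against WT (SE 0.0978, adjusted p = 6.89e-08) and fell by 3.07 in C185Gneo against WT (adjusted p = 5.93e-10). It was 1.67 higher in C185G than in C185Gneo (adjusted p = 1.14e-08). Sftpc took 0.717 to 0.747% of the counts of all measured genes in the WT libraries, 0.0756 to 0.108% in C185Gneo and 0.257 to 0.317% in C185G. The gene (ENSMUSG00000022097) lies on chromosome 14 from 70520949 to 70524081 on the minus strand in GRCm38. The residue that C185G names is a cysteine of the 193-residue protein, coded by TGT at 70521353 to 70521355 in exon 5, the last of the 5 exons that hold coding sequence. Quantile normalization, which gives every library the same distribution, left Sftpc lower in C185G than in WT by a smaller amount (-0.52, adjusted p = 0.00641; the adjusted p ran from 1.82e-08 to 0.00641 over all alternatives).

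**Figure D1:**
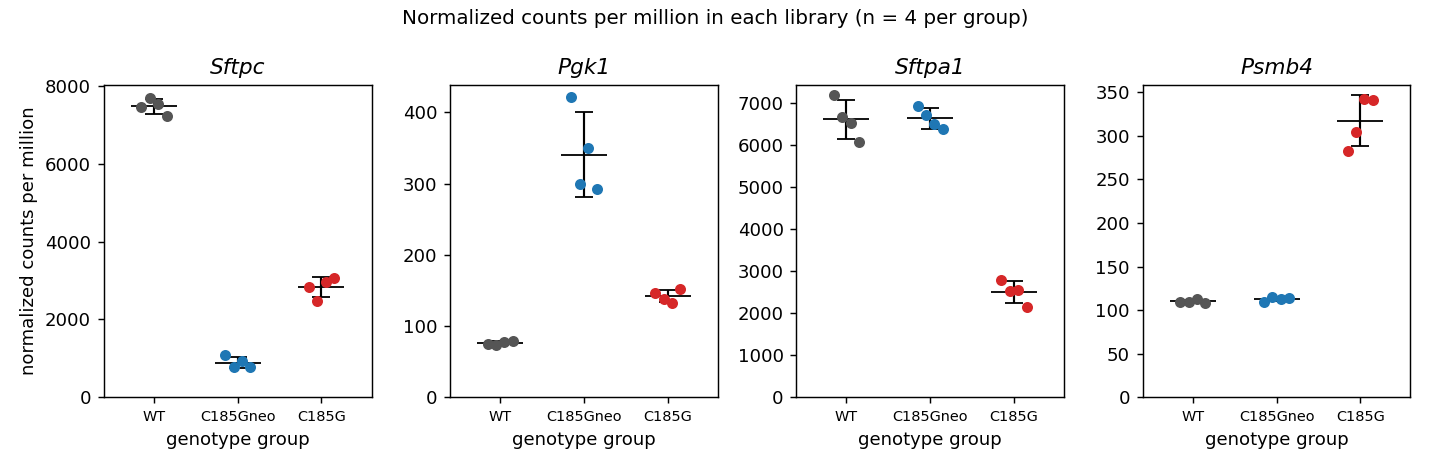
Normalized CPM (vertical axes, starting at 0) of Sftpc, Pgk1, Sftpa1 and Psmb4 in each library, by genotype group (horizontal axes). Points are libraries, wide bars are means and error bars are SD (n = 4). Sftpc averaged 7464 in WT, 895 in C185Gneo and 2832 in C185G, while Sftpa1 was low and Psmb4 high in C185G alone among the 3 groups.

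In C185G against WT, most measured genes of surfactant, lipid synthesis and MHC class II were lower, and most of the proteasome and of several stress responses were higher. These lists were called by camera at a preset correlation but not with an estimated correlation (smallest adjusted p = 0.268). Sftpa1, which encodes a surfactant collectin, fell from 6611 ± 460 to 2509 ± 261 normalized CPM (n = 4 each). Hc, the gene of complement component C5 and an AEC2 marker in mice, fell from 3324 ± 335 to 534 ± 59.6. All 31 measured proteasome subunit genes rose, among them Psmb4 of the core particle, from 110 ± 2.07 to 317 ± 28.9. Clu, which encodes a secreted chaperone, rose from 563 ± 12.2 to 2131 ± 138.

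The limma test called 8852 genes (55% of those measured) in this comparison, of which 4388 were higher and 4464 lower in C185G. Changes of more than 1 on the log2 scale numbered 812 higher and 1046 lower. The values of both groups did not overlap in 48.7% of all genes measured, where chance gives 2.86%. With library totals as the scaling, 5357 genes were higher and 3593 lower, so that 59.9% of the calls were higher in place of 49.6%.

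Uchl1, a ubiquitin C-terminal hydrolase of neurons and neuroendocrine cells, rose from 5.84 ± 0.445 to 104 ± 7.26 normalized CPM (log2 fold change 4.15, SE 0.0825, adjusted p = 9.78e-13). Afp, alpha-fetoprotein, rose by 3.96 (adjusted p = 3.73e-10), Prg4, lubricin, by 4.24 (adjusted p = 3.54e-09), and Adm2, a peptide hormone of the adrenomedullin family, by 3.86 (adjusted p = 6.24e-07). Mt3, a metallothionein, had 1 to 9 counts in each WT library and 428 to 656 in each C185G library (fitted log2 fold change 7.37, adjusted p = 8.66e-08). Sprr1a, a precursor of the cornified envelope, rose from 48.3 ± 15.4 to 686 ± 72.8, and Gsta1, a glutathione S-transferase, from 5.83 ± 0.383 to 87.8 ± 12.5. Both belong to families of near-identical genes, so their identity is uncertain. The variable-region gene Ighv14-4 is uncertain for the same reason: it had 0 to 4 counts in WT and 13 to 1371 in C185G, and its call (adjusted p = 0.00334) was lost with voom weights (adjusted p = 0.104).

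Among the largest decreases, Acoxl, an acyl-CoA oxidase-like gene, fell from 448 ± 57.9 to 29.8 ± 14.1 normalized CPM (-4.01, adjusted p = 2.6e-07), and Itih4, a heavy chain of the inter-alpha-trypsin inhibitor family, from 872 ± 189 to 61.8 ± 12.5 (-3.81, adjusted p = 1.18e-07). Fbn2, fibrillin 2, fell by 4.54 (adjusted p = 1.68e-09), Cst8, a cystatin family member, by 4.90 (adjusted p = 1.27e-07), Zmat4, a zinc finger gene, by 4.75 (adjusted p = 6.64e-07), Hes2, a transcriptional repressor, by 4.86 (adjusted p = 2.48e-05) and Proz, vitamin K-dependent protein Z, by 3.84 (adjusted p = 3.06e-07). Lyz1 fell from 1261 ± 151 to 81.9 ± 48.1 and Lyz2 from 5834 ± 324 to 1331 ± 301. These lysozyme genes share long stretches of sequence, and the split of reads between them is uncertain.

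Of the genes named in advance, Hspa5, the ER chaperone BiP, rose from 1183 ± 69.2 to 1881 ± 394 normalized CPM (0.65, adjusted p = 0.000337), while Xbp1, a transcription factor of the unfolded protein response, fell by 0.30 (adjusted p = 0.0015). The keratin gene Krt8 rose by 0.33 (adjusted p = 0.000546) and Cdkn1a, the cell cycle inhibitor p21, by 0.62 (adjusted p = 9.34e-05). Ddit3, which encodes CHOP, was 31.6 ± 2.78 in WT and 37.7 ± 8.97 in C185G and did not pass the test (0.23, adjusted p = 0.187), except when C185G replicate 2 was left out (0.39, adjusted p = 0.00603). Quantile normalization moved the changes of some abundant genes without ending their calls, to -0.78 for Sftpa1, 0.63 for Krt8 and 1.35 for Sqstm1. It ended the call of Cyp2f2, a club and goblet marker (-0.62 to -0.24, adjusted p = 0.206). The call of Calr, from the list of ATF6 targets and ER chaperones, also ended (-0.2 to -0.1, adjusted p = 0.118).

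Most members of the surfactant, lipid synthesis, MHC class II and immediate early lists and 9 of 17 endothelial markers were lower in C185G than in WT. The camera test with its preset correlation called 15 of 32 lists, of which none passed with an estimated correlation (smallest adjusted p = 0.268), and member counts from the gene test stand beside each. Of 23 surfactant and lamellar body genes of AEC2, 21 fell and 2 rose (21 and 2 adjusted over the list alone), with a median of -1.37 (camera adjusted p = 1.21e-10, and adjusted p = 0.268 with an estimated correlation). Besides Hc and Sftpa1, Chil1, a chitinase-like secreted protein, fell by 2.17 (adjusted p = 1.67e-09). The exceptions were Ctsh, cathepsin H, a protease of surfactant protein maturation (0.94), and Pgc, progastricsin (0.83). Cholesterol synthesis genes fell in 22 of 24 cases and rose in 1 (23 and 1 adjusted over the list alone). The median was -1.14 (camera adjusted p = 1.43e-09, and adjusted p = 0.268 with an estimated correlation). Dhcr7, a reductase of the last steps of the pathway, fell by 2.52, and the kinase gene Pmvk rose (1.73). In the list of fatty acid and phospholipid synthesis 20 of 25 genes fell and 0 rose (20 lower and 1 higher adjusted over the list alone), including the desaturase gene Fads1 (-1.67), the acyltransferase gene Gpam (-1.71) and Acly, ATP citrate lyase (-1.40). These genes had a median of -0.58 (camera adjusted p = 3.17e-07, and adjusted p = 0.268 with an estimated correlation). MHC class II genes fell in 8 of 9 cases (8 adjusted over the list alone), with H2-Aa down from 338 ± 30.1 to 74.8 ± 14 normalized CPM, Cd74 down by 1.23, and H2-Ob the exception (-0.07, adjusted p = 0.819). The list median was -1.69 (camera adjusted p = 1.01e-05, and adjusted p = 0.268 with an estimated correlation).

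Immediate early genes fell in 15 of 22 cases and rose in 2 (16 and 2 adjusted over the list alone). Their median stood at -0.46 (camera adjusted p = 0.00155, and adjusted p = 0.5 with an estimated correlation). Nr4a1, an orphan nuclear receptor, fell from 1387 ± 57.9 to 470 ± 45.7 normalized CPM and Klf2 by 1.04, whereas Myc (0.93) and the phosphatase gene Dusp1 (0.45) rose. Endothelial markers fell in 9 of 17 cases (9 adjusted over the list alone), among them Tie1 (-1.17), Vwf (-1.08) and Egfl7 (-0.79). Without WT replicate 4 this list missed the threshold (adjusted p = 0.0587, median -0.44). Over the list the median was -0.75 (camera adjusted p = 0.0214, and adjusted p = 0.568 with an estimated correlation).

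Proteasome genes were higher in C185G than in WT. All 31 subunit genes passed the test, between 0.93 and 1.76 (31 adjusted over the list alone). Camera gave adjusted p = 1.04e-24 for a median of 1.36, and adjusted p = 0.268 with an estimated correlation. Psma5 rose by 1.69 and Psmc2, an ATPase of the regulatory particle, by 1.55. In ER-associated degradation, the route that takes misfolded proteins out of the ER, 10 of 17 genes rose and 2 fell (10 and 2 adjusted over the list alone). The members had a median of 0.26 (camera adjusted p = 0.00215, and adjusted p = 0.293 with an estimated correlation). Vcp, its ATPase, rose by 0.87 and the VCP cofactor genes Nploc4 and Ufd1 by 1.37 and 1.27, while Selenos (-0.38) and Edem3 (-0.23) fell.

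Stress responses showed rising members too. PERK-ATF4 genes rose in 22 of 35 cases and fell in 5 (22 and 5 adjusted over the list alone). For a median of 0.64 the camera test gave adjusted p = 5.77e-06, and adjusted p = 0.268 with an estimated correlation. Asns, asparagine synthetase, rose by 1.45, the amino acid transporter gene Slc7a3 by 2.01 and the tRNA synthetase genes Aars and Nars by 0.96 and 0.85. The 5 that fell were transcription factors and feedback or sulfur metabolism genes: Atf4 (-0.40), Atf3 (-0.71), Cebpb (-0.41), Ppp1r15a (-0.38) and Cth (-0.57). Targets of NRF2, the regulator of antioxidant defence, rose in 18 of 21 cases and fell in 1, Gstm1 (18 and 1 adjusted over the list alone), with Taldo1 of the pentose phosphate pathway up by 1.78, the quinone reductase gene Nqo1 by 1.80 and Prdx1, a peroxiredoxin, by 1.03. The median was 1.01 (camera adjusted p = 6.85e-08, and adjusted p = 0.268 with an estimated correlation). Cytosolic heat shock genes rose in 13 of 17 cases and fell in 1, Hsf1 (13 and 1 adjusted over the list alone). These genes had a median of 0.78 (camera adjusted p = 5.34e-06, and adjusted p = 0.376 with an estimated correlation). The list also holds genes of the mitochondrial chaperonin, of which Hspd1 rose by 1.40. Hspa1b (3.30) and Hspa1a (1.93) are near-identical genes, so only their joint rise is certain. Targets of p53 rose in 14 of 20 cases and fell in 2, Btg2 and Sesn1 (14 and 2 adjusted over the list alone), with Bax up by 1.12, Ccng1 by 1.24 and Phlda3 by 1.78. The list median was 0.45 (camera adjusted p = 0.000196, and adjusted p = 0.268 with an estimated correlation).

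Genes of the alveolar transitional state, which epithelial cells pass through between the AEC2 and alveolar type 1 identities, rose in 19 of 27 cases and fell in 2 (19 and 2 adjusted over the list alone). Their median stood at 0.53 (camera adjusted p = 3.17e-07, and adjusted p = 0.268 with an estimated correlation). Next to Clu, Lgals3, galectin 3, rose from 308 ± 37 to 898 ± 108 normalized CPM and Cstb, a cystatin, by 1.49, while Krt20 (-2.16) and Hbegf (-0.21) fell. Oxidative phosphorylation genes rose in 34 of 43 cases and fell in 0 (34 and 0 adjusted over the list alone), with Uqcrq up by 0.99 and Ndufa10 by 0.87. Over the list the median was 0.32 (camera adjusted p = 8.12e-09, and adjusted p = 0.268 with an estimated correlation). Cell cycle genes rose in 24 of 30 cases and fell in 2 (26 and 2 adjusted over the list alone). Camera gave adjusted p = 2.51e-06 for a median of 1.36, and adjusted p = 0.379 with an estimated correlation. Rrm2, a ribonucleotide reductase subunit, rose from 3.09 ± 0.348 to 11.3 ± 2.55 normalized CPM and Mcm5, part of the replicative helicase, by 1.49, whereas the spindle checkpoint genes Bub1 (-1.56) and Bub1b (-0.48) fell. Calls of several list exceptions were lost when 1 library was left out: Cebpb without WT 3 or 4 or C185G 1, 2 or 4 (adjusted p = 0.056 to 0.082), Edem3 without WT 1 or 2 or C185G 2 (0.055 to 0.0608), Hbegf without WT 1 or C185G 2 or 4 (0.0644 to 0.0714), Hsf1 without WT 3 or C185G 3 (0.0547 and 0.0557) and Bub1b without WT 2 (0.0503). With library totals as the scaling Edem3 (0.0745) and Hbegf (0.113) lost theirs too.

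**Figure D2:**
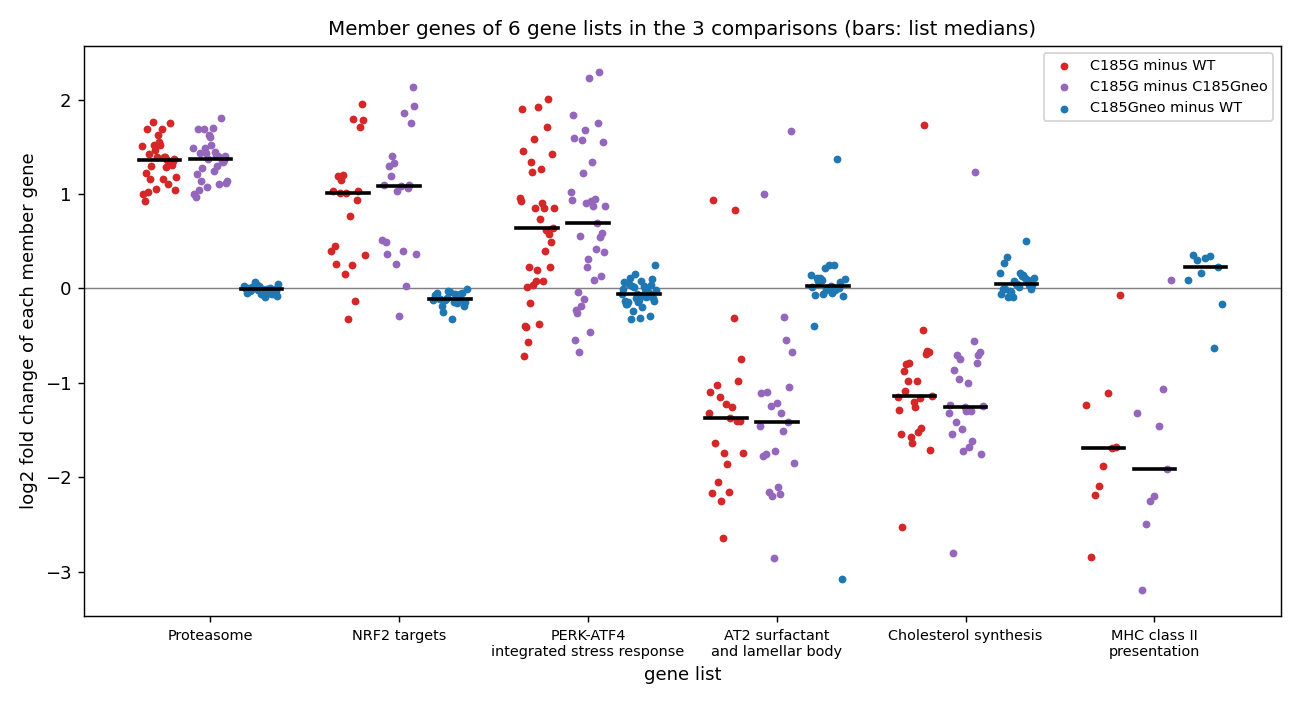
Log2 fold change (vertical axis) of each measured member of 6 gene lists (horizontal axis) in the 3 comparisons, by colour. Each point is a gene and each bar a list median; proteasome genes had medians of 1.36 and 1.37 in C185G against WT and against C185Gneo and of -0.01 in C185Gneo against WT, where library totals as the scaling gave 0.01.

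Other lists did not pass the camera test in C185G against WT. With 55% of all genes called, their member counts alone do not set them apart from other genes. Targets of IRE1 and XBP1, which serve ER protein folding and secretion, had 3 of 25 members higher, Ssr3 (0.23) among them, and 8 lower (3 and 6 adjusted over the list alone, median -0.05, adjusted p = 0.385), with Pdia6 at -0.42 and Ssr1 at -0.36. The sign of this median turned with library totals as the scaling (0.03). ATF6 targets and ER chaperones had 6 of 18 higher and 3 lower (6 and 2 adjusted over the list alone, median 0.01, adjusted p = 0.448), with Sdf2l1 (0.63) and Sel1l (0.52) up next to Hspa5, and Herpud1 (-0.46) down. Autophagy genes had 10 of 22 higher and 3 lower (11 and 3 adjusted over the list alone, median 0.10, adjusted p = 0.135), including the receptor gene Sqstm1 from 1636 ± 132 to 2880 ± 275 normalized CPM and Gabarapl1 by 0.80, with Map1lc3b lower (-0.27). Lysosomal genes had 12 of 27 higher and 3 lower (12 and 3 adjusted over the list alone, median 0.09, adjusted p = 0.0836), led by the cathepsin genes Ctsd (1.29) and Ctsz (0.99). Leaving out WT 1 or C185G 1 gave adjusted p = 0.0488 and 0.0409. Glycolysis had 9 of 18 higher, Pkm (1.22) and Eno1 (1.15) among them, and 3 lower, including Pfkl at -0.46 (9 and 3 adjusted over the list alone, median 0.21, adjusted p = 0.0805). TGF-beta and matrix remodelling genes had 15 of 28 higher and 7 lower (15 and 8 adjusted over the list alone, median 0.44, adjusted p = 0.068, and 0.0479 without WT 1), with Itgav (1.07) and Timp1 (2.45) up. With quantile normalization the lysosome and the TGF-beta lists passed (adjusted p = 0.0225 and 0.0293), and with library totals the lysosome list did (0.0343).

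Alveolar type 1 markers went both ways, with 6 of 22 higher and 3 lower (6 and 3 adjusted over the list alone, median 0.13, adjusted p = 0.627), as in Prdx6 (0.74), Vegfa (-0.67) and Ager (-0.32). Cytokine and chemokine genes had 12 of 29 higher and 7 lower (12 and 7 adjusted over the list alone, median 0.33, adjusted p = 0.347). Saa3, an acute-phase protein, rose from 1.99 ± 0.52 to 22.4 ± 6.92 normalized CPM, while Il33 (-1.17) and Cx3cl1 (-0.89) fell. Interferon response genes had 4 of 31 higher, Rsad2 (2.56) and Oas3 (1.76) among them, and 9 lower, Stat2 (-0.79) among them (4 and 8 adjusted over the list alone, median -0.15, adjusted p = 0.347).

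Markers of other lung and blood cell types, measured in the same libraries, went in no common direction in C185G against WT. Neutrophil and monocyte markers had 6 of 12 higher and 1 lower (6 and 1 adjusted over the list alone, median 1.25, adjusted p = 0.201), with S100a8 at 2.49, Plac8 at 0.91 and Ly6c2 at -0.79. Macrophage markers had 4 of 14 higher and 2 lower (3 and 2 adjusted over the list alone, median 0.11, adjusted p = 0.753), with Cd68 (0.94) and Chil3 (1.69) up and Lpl (-1.02) down. Lymphocyte markers had 0 of 6 higher and 3 lower (0 and 3 adjusted over the list alone, median -0.24, adjusted p = 0.406), Ighm (-0.91) among them. Mesenchymal markers had 3 of 21 higher and 2 lower (1 and 0 adjusted over the list alone, median 0.36, adjusted p = 0.456). Club and goblet markers had 0 of 15 higher and 5 lower (0 and 4 adjusted over the list alone, median -0.26, adjusted p = 0.13, and 0.0338 without WT 1), with Cbr2 from 4113 ± 312 to 2348 ± 169 normalized CPM (-0.81, and -0.39 with quantile normalization). Ciliated markers had 1 of 19 higher, Mcidas (1.18), and 8 lower, such as Dnah11 at -0.69 (1 and 8 adjusted over the list alone, median -0.35, adjusted p = 0.0502, and 0.0108 to 0.0248 without WT 1, WT 2, C185G 1 or C185G 2). Quantile, library-total and median-of-ratios scaling also brought ciliated markers under the threshold (0.0486, 0.0446 and 0.046). Basal and neuroendocrine markers had 2 of 9 higher, Uchl1 and Calca (1.75), and 2 lower, Syp (-1.07) and Krt15 at -0.65 (2 and 2 adjusted over the list alone). Their median was -0.30 but their mean 0.51, and the test pointed up (adjusted p = 0.627). Mesothelial markers had 1 of 9 higher and 0 lower (1 and 0 adjusted over the list alone, median 0.43, adjusted p = 0.294).

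Against C185Gneo, the control with the lower Sftpc level, most surfactant and lipid genes were again lower in C185G and most proteasome and stress genes higher, although Sftpc itself was higher. As against WT, these lists were called by camera at a preset correlation but not with an estimated correlation (smallest adjusted p = 0.262). Sftpa1 fell from 6636 ± 241 to 2509 ± 261 normalized CPM, Hc from 3857 ± 70.6 to 534 ± 59.6 and Acly from 1140 ± 49.7 to 413 ± 40.8 (n = 4 each). Psmb4 rose from 113 ± 2.38 to 317 ± 28.9, Clu from 596 ± 71.5 to 2131 ± 138 and Taldo1 from 137 ± 10.2 to 522 ± 37. With quantile normalization Sftpa1 fell by 0.91 in place of 1.41. The limma test called 9298 genes (57.8% of those measured), 4691 higher and 4607 lower in C185G, of which 1030 and 1115 changed by more than 1 on the log2 scale. With library totals as the scaling, 5437 were higher and 3923 lower (58.1% higher in place of 50.5%). Both groups were free of overlap in 49.9% of all genes measured (2.86% by chance).

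Several of the largest changes were those seen against WT: Mt3 (6.91, adjusted p = 1.27e-07) and Sprr1a (4.81, adjusted p = 5.32e-09) rose, and Cst8 (-5.73), Zmat4 (-5.63), Fbn2 (-5.05), Hes2 (-5.03), Acoxl (-4.37) and Lyz1 (-4.28) fell. Saa3 rose from 1.15 ± 0.263 to 22.4 ± 6.92 normalized CPM (4.22, adjusted p = 1.92e-08). Nrn1, neuritin, fell from 113 ± 12.1 to 5.06 ± 2.79 (-4.60, adjusted p = 7.57e-08) and Avpr1a, a vasopressin receptor, from 15.1 ± 1.12 to 0.495 ± 0.308 (-5.12, adjusted p = 7.36e-07). The remaining large increases were immunoglobulin genes, which share sequence with their relatives and are uncertain one by one: Ighg1 (6.04, adjusted p = 0.000524), Ighg2c (4.51, adjusted p = 0.00044), Igkv3-10 (4.31, adjusted p = 0.000162) and Igkv8-21 (4.24, adjusted p = 0.00442). Over all immunoglobulin genes the median was 1.65 here, 0.43 against WT and -1.27 in C185Gneo against WT. The difference was thus larger against C185Gneo than against WT. Igkv4-57 (4.70, adjusted p = 0.0315) lost its call without C185Gneo 1 or 2 or C185G 2 or 3 (adjusted p = 0.0766 to 0.0825) and with voom weights (0.113). Hspa5 rose by 0.56 (adjusted p = 0.00105), Ddit3 by 0.55 (adjusted p = 0.00473), Krt8 by 0.50 (adjusted p = 1.64e-05) and Cdkn1a by 0.79 (adjusted p = 9.76e-06), and Xbp1 fell by 0.29 (adjusted p = 0.00215).

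The lower gene groups were largely those seen against WT. Of all genes measured, 57.8% were called against C185Gneo, 4691 higher and 4607 lower. Member counts near that share do not set a list apart, here and in the lists that follow. Surfactant and lamellar body genes fell in 21 of 23 cases and rose in 2, Sftpc and Ctsh (21 and 2 adjusted over the list alone). The members had a median of -1.41 (camera adjusted p = 1.33e-09, and adjusted p = 0.262 with an estimated correlation). Cholesterol synthesis genes fell in 23 of 24 cases and rose in 1, Pmvk (23 and 1 adjusted over the list alone), with Dhcr7 at -2.80. For a median of -1.25 the camera test gave adjusted p = 1.33e-09, and adjusted p = 0.262 with an estimated correlation. In fatty acid and phospholipid synthesis 20 of 25 fell and 1 rose, the choline pathway gene Pcyt1a (20 and 1 adjusted over the list alone), with Gpam at -1.95 and Fads1 at -1.91. The median was -0.58 (camera adjusted p = 4.45e-07, and adjusted p = 0.262 with an estimated correlation). MHC class II genes fell in 8 of 9 cases (8 adjusted over the list alone), with H2-Aa at -2.50. These genes had a median of -1.91 (camera adjusted p = 1.59e-05, and adjusted p = 0.262 with an estimated correlation). Immediate early genes fell in 15 of 22 cases and rose in 3, Myc and Dusp1 among them (15 and 3 adjusted over the list alone), a call that quantile normalization ended (adjusted p = 0.0533). The list median was -0.38 (camera adjusted p = 0.00842, and adjusted p = 0.597 with an estimated correlation). Endothelial markers fell in 12 of 17 cases (13 adjusted over the list alone). Their median stood at -0.76 (camera adjusted p = 0.00704, and adjusted p = 0.503 with an estimated correlation). Markers of club and goblet cells, the secretory cells of the airway, fell in 10 of 15 cases (10 adjusted over the list alone), with the mucin gene Muc5b at -1.40, the trefoil factor gene Tff2 at -1.72 and Bpifa1, a secreted airway protein, at -2.48. Over the list the median was -0.60 (camera adjusted p = 0.00312, and adjusted p = 0.503 with an estimated correlation). Club and goblet markers did not pass the camera test against WT (median -0.26, adjusted p = 0.13). In C185Gneo against WT they had a mean of 0.59 and a median of 0.02, so part of this fall lay in the control.

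Among the groups that rose against C185Gneo, all 31 proteasome genes did so (31 adjusted over the list alone). Camera gave adjusted p = 2.22e-23 for a median of 1.37, and adjusted p = 0.262 with an estimated correlation. ER-associated degradation rose in 9 of 17 cases and fell in 1, Selenos (9 and 1 adjusted over the list alone). The members had a median of 0.22 (camera adjusted p = 0.00815, and adjusted p = 0.367 with an estimated correlation). PERK-ATF4 genes rose in 24 of 35 cases and fell in 4, Atf3, Cth and Ppp1r15a among them (24 and 4 adjusted over the list alone), with Asns up by 1.59. For a median of 0.70 the camera test gave adjusted p = 3.23e-06, and adjusted p = 0.262 with an estimated correlation. NRF2 targets rose in 18 of 21 cases and fell in 1, Gstm1 (18 and 1 adjusted over the list alone). The NRF2 median was 1.09 (camera adjusted p = 8.58e-09, and adjusted p = 0.262 with an estimated correlation). Heat shock genes rose in 13 of 17 cases (13 adjusted over the list alone). Their median was 0.84 (camera adjusted p = 2.35e-06, and adjusted p = 0.367 with an estimated correlation). Transitional state genes rose in 24 of 27 cases and fell in 1, Krt20 (24 and 1 adjusted over the list alone), with Lgals3 up by 1.83. The median was 0.78 (camera adjusted p = 5.88e-09, and adjusted p = 0.262 with an estimated correlation). Targets of p53 rose in 13 of 20 cases and fell in 2, Btg2 and Sesn1 (14 and 2 adjusted over the list alone). These genes had a median of 0.45 (camera adjusted p = 0.000188, and adjusted p = 0.262 with an estimated correlation). Oxidative phosphorylation genes rose in 31 of 43 cases and fell in 2, Ndufb3 (-0.33) and Ndufb10 at -0.13 (31 and 2 adjusted over the list alone). The call of Ndufb10 was lost without C185Gneo 1 or 3 or C185G 4 (adjusted p = 0.056 to 0.0797) and with library totals (0.241). The list median was 0.26 (camera adjusted p = 1.9e-06, and adjusted p = 0.367 with an estimated correlation). Cell cycle genes rose in 24 of 30 cases and fell in 1, Bub1 (24 and 1 adjusted over the list alone). Their median stood at 1.08 (camera adjusted p = 2.56e-05, and adjusted p = 0.454 with an estimated correlation).

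TGF-beta and matrix genes, mesenchymal markers and mesothelial markers, like the club and goblet markers above, passed the camera test here and did not against WT. Of the TGF-beta and matrix list 17 of 28 rose and 3 fell (17 and 4 adjusted over the list alone), with Timp1, an inhibitor of matrix proteases, up by 3.23. Over the list the median was 0.49 (camera adjusted p = 0.00593, and adjusted p = 0.262 with an estimated correlation). Mesenchymal markers rose in 14 of 21 cases (14 adjusted over the list alone), among them Mgp from 67.9 ± 25.9 to 183 ± 30.9 normalized CPM and Dcn, decorin, by 1.68. Camera gave adjusted p = 0.00467 for a median of 0.74, and adjusted p = 0.597 with an estimated correlation. Mesothelial markers rose in 4 of 9 cases (4 adjusted over the list alone), a list call lost without C185G replicate 2 (adjusted p = 0.0524) and with library totals as the scaling (0.0668). The members had a median of 1.07, or 0.57 without C185Gneo replicate 1 (camera adjusted p = 0.0371, and adjusted p = 0.605 with an estimated correlation). Msln rose by 1.73 and Wt1 by 1.72, and by 1.12 and 1.04 without C185Gneo replicate 1. Whether these lists differ between both comparisons was tested only through C185Gneo against WT.

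Lists that did not pass against C185Gneo were alveolar type 1 markers (6 of 22 higher, 2 lower; 6 and 2 adjusted over the list alone, median 0.19, adjusted p = 0.344) and IRE1-XBP1 targets (3 of 25 higher, 11 lower; 3 and 11 adjusted over the list alone, median -0.10, adjusted p = 0.0573, and 0.0318 or 0.0229 without C185Gneo 2 or C185G 2). ATF6 targets had 4 of 18 higher and 4 lower (4 and 4 adjusted over the list alone, median -0.05, adjusted p = 0.613), with a median that turned to 0.02 with library totals as the scaling. Autophagy had 9 of 22 higher and 5 lower (10 and 5 adjusted over the list alone, adjusted p = 0.273), lysosome 10 of 27 and 5 (10 and 5 adjusted over the list alone, adjusted p = 0.136) and glycolysis 9 of 18 and 4, with Pgk1 among the lower (9 and 4 adjusted over the list alone, adjusted p = 0.139). Cytokines had 11 of 29 higher and 6 lower (12 and 6 adjusted over the list alone, adjusted p = 0.259) and interferon response genes 9 of 31 and 6 (9 and 6 adjusted over the list alone, adjusted p = 0.613). Macrophage markers had 5 of 14 higher and 1 lower (5 and 1 adjusted over the list alone, adjusted p = 0.259), neutrophil and monocyte markers 7 of 12 and 1 (7 and 1 adjusted over the list alone, adjusted p = 0.0947, and 0.0415 or 0.0438 without C185Gneo 2 or C185G 3), and lymphocyte markers 0 of 6 and 3 (0 and 3 adjusted over the list alone, adjusted p = 0.604). Ciliated markers had 1 of 19 higher and 8 lower (1 and 5 adjusted over the list alone, adjusted p = 0.0533, and 0.0122 to 0.0186 without C185Gneo 1, C185G 1 or C185G 2 and 0.0486 with median-of-ratios scaling), and basal and neuroendocrine markers 3 of 9 higher and 2 lower (3 and 2 adjusted over the list alone, adjusted p = 0.572).

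Most of the genes that changed in C185G did so against both controls. Of the calls against WT, 7909 (89.3%) were also made against C185Gneo in the same direction, 3928 higher and 3981 lower. With library totals as the scaling, the genes called against both were 4739 higher and 3232 lower, so that 59.5% were higher in place of 49.7%. Independent lists of these sizes would share 1280 higher and 1279 lower genes, and simulated unchanged groups that share the C185G libraries gave 0.05 shared calls on average and at most 1 in 20 simulations. With no gene changed few calls are made at all, so this simulated count does not measure what sharing the libraries adds to the overlap. The log2 fold changes correlated across genes at r = 0.918 (0.509 in the simulations; genes are not independent replicates), with a covariance of 0.521 against 0.0218 simulated. When the C185G libraries were split so that each comparison had its own pair, 5323 to 5643 genes were shared over the 6 splits and r was 0.818 to 0.871.

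The plot of both comparisons shows 10 genes called in opposite directions. Sftpc and Lemd1 (-2.04 and 2.65) were lower than in WT and higher than in C185Gneo. Pgk1 (0.90 and -1.24), which encodes the glycolytic enzyme phosphoglycerate kinase 1, Camk2b (0.67 and -1.40), a calmodulin-dependent kinase, and Pgc (0.83 and -0.54) were higher than in WT and lower than in C185Gneo, as were Cd59a, Efcab7 and 3 pseudogenes or predicted genes. Cd59a lost its call against C185Gneo without C185G 1, 2 or 3 (adjusted p = 0.05 to 0.0672) and Efcab7 without C185Gneo 2 or C185G 2 or 3 (0.0694 to 0.0869). Lemd1 and Efcab7 were named here after their values were seen.

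**Figure D3:**
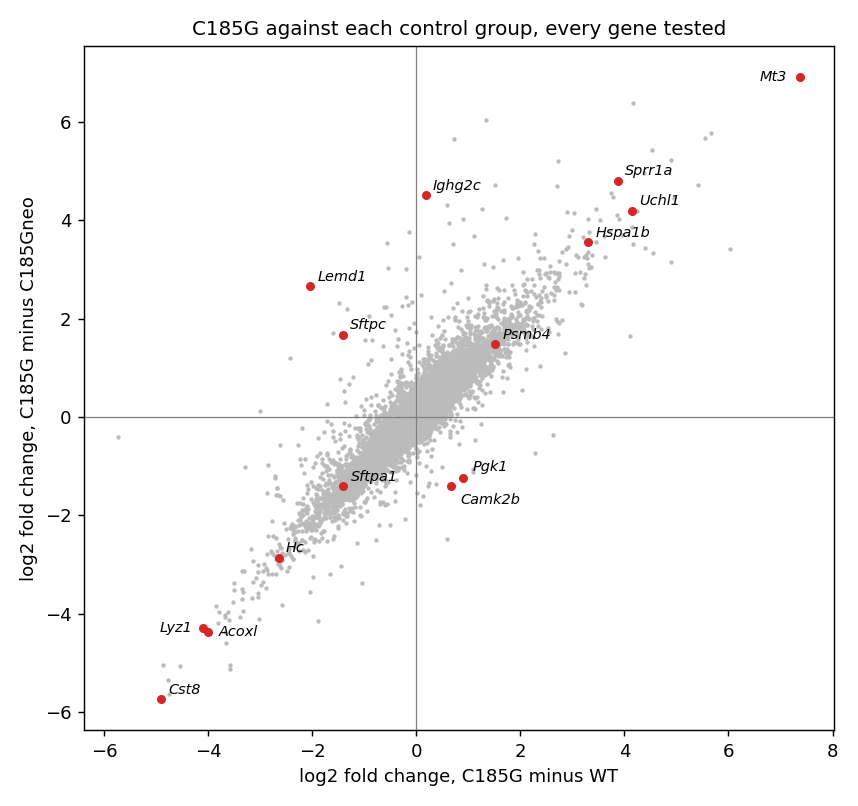
Log2 fold change of every gene tested in C185G against WT (horizontal axis) and against C185Gneo (vertical axis), with 15 named genes in red. Most genes lie near the diagonal (r = 0.918); Sftpc (-1.40 and 1.67) and Pgk1 (0.90 and -1.24) lie in the opposite quadrants.

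C185Gneo against WT compares the control genotypes with each other and differed in far fewer genes. Apart from Sftpc, Pgk1 rose most clearly, from 76.1 ± 2.55 to 341 ± 59.5 normalized CPM (2.15, SE 0.0948, adjusted p = 3.41e-08; n = 4 each). Pgk1 (ENSMUSG00000062070) lies on chromosome X from 106187100 to 106203699 on the plus strand (GRCm38). Camk2b rose from 11.6 ± 2.25 to 48.3 ± 6.23 (2.06, adjusted p = 0.00043), Cd59a, a complement inhibitor, from 9.6 ± 1.29 to 28.9 ± 1.47 (adjusted p = 0.000313) and Pgc from 5.53 ± 0.336 to 14.6 ± 3.22 (1.37, adjusted p = 0.00043). Ly6i, an Ly6 family antigen, fell from 46.4 ± 22.5 to 4.88 ± 1.02 (-3.12, adjusted p = 0.00203). In C185G the level of Ly6i was 5.46 ± 1.79, and that of Pgk1 143 ± 8.38.

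The limma test called 87 genes (0.541% of those measured) in C185Gneo against WT, 40 higher and 47 lower, with 25 of each beyond 1 on the log2 scale. The groups did not overlap in 6.87% of all genes measured (2.86% by chance), and 1534 genes had an unadjusted p under 0.05. The number of called genes fell to 40 without WT 1, 45 without WT 3, 51 without WT 4 and 43, 42 and 44 without C185Gneo 1, 2 and 3. Some of the largest differences depended on single libraries. Muc5b, at 174 ± 51.1 in WT and 526 ± 58.3 in C185Gneo (1.64, adjusted p = 0.0141), lost its call without C185Gneo 1 or 3 (0.0573 and 0.0591). Fgg, a fibrinogen chain (1.72, adjusted p = 0.0323), lost it whichever of the 8 libraries was left out (0.0531 to 0.114). The immunoglobulin genes Ighg2c (-4.33, adjusted p = 0.0369) and Ighg2b (-3.89, adjusted p = 0.0494) lost theirs in every case except without WT 2 (up to 0.143 and 0.176), and Igkv3-10 (-3.72, adjusted p = 0.0323) in every case except without WT 2 or C185Gneo 4 (up to 0.116). With voom weights Ighg2c, Ighg2b and Igkv3-10 were at 0.277, 0.206 and 0.317. Hspa5 (0.09, adjusted p = 0.878), Xbp1 (-0.02, adjusted p = 0.969), Ddit3 (-0.32, adjusted p = 0.496), Krt8 (-0.17, adjusted p = 0.406) and Cdkn1a (-0.18, adjusted p = 0.606) did not pass the test.

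In C185Gneo against WT few members of the lists passed the test for single genes. The smallest camera p was that of mesenchymal markers, with 0 of 21 called (0 higher and 7 lower adjusted over the list alone). Mesenchymal genes had a median of -0.67 (camera adjusted p = 5.01e-10, and adjusted p = 0.56 with an estimated correlation), which was -0.39 without C185Gneo 1 (adjusted p = 4.67e-07). Mesothelial markers had 0 of 9 called (0 adjusted over the list alone) and a median of -0.69 (camera adjusted p = 0.000926, and adjusted p = 0.612 with an estimated correlation). The mesothelial call was lost without C185Gneo 1 (median -0.14, adjusted p = 0.268), and the median was -1.07 without C185Gneo 4. Club and goblet markers had 1 of 15 higher, Muc5b (5 adjusted over the list alone). For a median of 0.02 and a mean of 0.59 the camera test gave adjusted p = 0.00054, and adjusted p = 0.612 with an estimated correlation. This median turned to -0.02 without WT 1 and lay between 0.01 and 0.08 without each of the other 7 libraries, while the mean ran from 0.47 to 0.73. Interferon response genes had 0 of 31 called (0 adjusted over the list alone) and a median of -0.30, or -0.19 without WT 3 (camera adjusted p = 4e-06, and adjusted p = 0.56 with an estimated correlation). Transitional state genes had 1 of 27 lower, Areg (2 adjusted over the list alone), and a median of -0.15 (camera adjusted p = 5.83e-07, and adjusted p = 0.412 with an estimated correlation). Macrophage markers had 1 of 14 lower, Mrc1 (2 adjusted over the list alone), and a median of -0.25 (camera adjusted p = 0.03, and adjusted p = 0.56 with an estimated correlation). Areg lost its call without WT 1 or 4 or C185Gneo 1 or 2 (adjusted p = 0.0549 to 0.0612), and Mrc1 in every case except without WT 2 or C185Gneo 4 (up to 0.0884). The macrophage list lost its own without WT 1 or C185Gneo 1 (0.112 and 0.146), the latter with a median of -0.12.

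A further set of lists passed the preset-correlation test in C185Gneo against WT with medians between -0.12 and 0.23 and with 0 members called by limma over all genes. Of all genes measured, 1534 had an unadjusted p under 0.05 in this comparison, and fry called 0 of the 32 lists. They were TGF-beta and matrix genes (0 higher and 2 lower adjusted over the list alone, median -0.12, adjusted p = 0.000817), NRF2 targets (median -0.11, adjusted p = 0.000273), immediate early genes (1 lower adjusted over the list alone, median -0.09, adjusted p = 0.00332), heat shock genes (median -0.08, adjusted p = 0.0255), PERK-ATF4 genes (median -0.06, adjusted p = 0.0351), oxidative phosphorylation (median 0.06, adjusted p = 3.4e-05), IRE1-XBP1 targets (median 0.07, adjusted p = 0.000685), ATF6 targets (1 higher adjusted over the list alone, median 0.09, adjusted p = 3.4e-05), cell cycle genes (median 0.21, adjusted p = 0.00658) and MHC class II genes (median 0.23, adjusted p = 0.0366), with 0 members adjusted over the list alone where none is given. With an estimated correlation their adjusted p-values were 0.412 to 0.718. The calls of 5 of them were lost without single libraries: cell cycle without WT 3 or C185Gneo 1 (0.148 and 0.373), heat shock without WT 4 or C185Gneo 1 or 2 (0.0843 to 0.44), immediate early without WT 3 or C185Gneo 1 (0.298 and 0.146), MHC class II without WT 3 or 4 or C185Gneo 1 or 3 (0.0576 to 0.271) and PERK-ATF4 without WT 1 or 3 or C185Gneo 3 (0.101 to 0.483). With voom weights PERK-ATF4 missed the threshold too (0.0615). Medians moved by more than 1.5 times without C185Gneo 1 for cell cycle (0.04), heat shock (-0.02), immediate early (-0.06), MHC class II (0.14), NRF2 (-0.06) and TGF-beta and matrix genes (-0.07). Heat shock was also at -0.02, -0.16 and -0.15 without C185Gneo 2, 3 and 4, immediate early at -0.15 and -0.05 without WT 1 and 3, NRF2 at -0.18 without C185Gneo 4 and PERK-ATF4 at -0.02 without C185Gneo 3. The other 16 lists did not pass (adjusted p = 0.0916 to 0.96), among them the proteasome (median -0.01, turning to 0.01 with library totals as the scaling, adjusted p = 0.567), surfactant and lamellar body genes (Pgc higher and Sftpc lower among 23, 1 and 2 adjusted over the list alone, median 0.02, mean -0.04, adjusted p = 0.626), cholesterol synthesis (median 0.05, adjusted p = 0.0916) and endothelial markers (median 0.09, adjusted p = 0.282). Some of these passed when 1 library was left out: cholesterol synthesis without WT 1, WT 2 or C185Gneo 3 (0.00216 to 0.00563), fatty acid synthesis without WT 1 or 2 (0.0373 and 0.0449) and alveolar type 1 markers without WT 2, WT 3 or C185Gneo 3 (0.00832 to 0.0304). Cytokines passed without WT 2 or C185Gneo 4 (0.0304 and 0.0036), neutrophil markers without WT 4 or C185Gneo 2 (0.0418 and 0.0278) and endothelial markers without WT 4 (0.0196).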

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

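Splits of the samples, the share of AEC2 and both tests on Pgk1 were chosen only after the results were seen; the proteasome tests were set before theirs.

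Other splits of the same libraries were counted for each result across genes. Only the real split of 35 gave as many genes in C185G against WT (1 of 35; 8852 genes, at most 0 in any other split), against C185Gneo (1 of 35; 9298 and 0) and in C185Gneo against WT (1 of 35; 87 and 0). For genes changed against both controls it was 1 of 100 regroupings (7909 and 0). These shares are the smallest that the 35 splits and 100 regroupings can give, so chance is argued against only to that limit. Splits that mix the genotypes also carry the difference between them into the spread within groups, which lowers their counts. Nor do the splits tell genotype from any other difference between the groups of samples. Chance is not argued against for the number of lists called by camera with a preset correlation. There, 13 of 35 splits reached the 15 lists of C185G against WT (highest other 21), 9 of 35 the 19 against C185Gneo (23) and 7 of 35 the 16 in C185Gneo against WT (24). The other 12 and 8 splits that did so with C185G kept 3 libraries of a genotype together and with them part of its difference, and the 18 splits with 2 libraries of each genotype on either side gave 3 to 14 lists against WT and 2 to 12 against C185Gneo. In C185Gneo against WT 3 of these 18 reached the 16 lists (highest 19). In an exact permutation of list means, two-sided, 22 of 32 lists against WT, 24 against C185Gneo and 4 in C185Gneo against WT reached the smallest p the design allows (0.0286), and 22, 24 and 0 stayed under the threshold after adjustment. This permutation asks whether a list differs at all, and not whether it differs more than other genes. Of all single genes, 48.7, 49.9 and 6.87% already had groups without overlap in these comparisons. It therefore does not set the lists apart from the rest of the genes.

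All 31 proteasome subunit genes rose in C185G. Removing trends with transcript length, GC content and mean level left their median at 1.336 against WT (1.357 before, SD 0.233 over members), which argues against such a bias as the cause. An interferon-induced immunoproteasome is argued against too, since 0 of its 3 subunit genes rose against both controls; Psmb10 was at -0.65 against WT. Of 12 assembly factors, activators and deubiquitinases of the proteasome, 9 rose against both controls, among them Usp14 (1.41) and Pomp (0.99). A coordinated rise of the wider proteasome programme may therefore underlie the pattern, as a hypothesis found on these data, and its regulator was not tested.

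Against WT, 21 of 23 surfactant genes fell in C185G and so did 9 of 17 endothelial markers, list calls not made with an estimated correlation (adjusted p = 0.268 and 0.568), the endothelial one also lost without WT 4 (adjusted p = 0.0587, median -0.44). If fewer AEC2, with the other cells in fixed proportions, were the whole cause, markers of every other lung cell type would rise alike. The mesenchymal list mean instead rose relative to the endothelial one by 0.75 against WT (SE 0.243, 95% interval 0.2 to 1.299) and by 1.447 against C185Gneo (0.898 to 1.997). Against WT the mesenchymal mean moved by 0.183 and the endothelial one by -0.566. The same lists moved apart in C185Gneo against WT, with the mesenchymal mean at -0.6 and the endothelial one at 0.098. There the surfactant mean moved by -0.04 only. The gap thus shifted between groups without a fall of surfactant genes, so it does not decide on a lower share of AEC2. A lower share, alone or together with shifts among the other cell types, therefore stays open as a cause of the surfactant fall. A change of expression within AEC2, the genotype effect that the design names, stays open as a hypothesis as well. A change in single other cell types stays open too.

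Pgk1 was highest in C185Gneo. A general rise of glycolytic transcripts is argued against: the median of the other 17 glycolysis genes was -0.04 (SD 0.111, 0 called by limma). Pgk1 was lower in C185G than in C185Gneo (-1.243), and its excess over WT in C185G was 25.1% of that in C185Gneo. In C185G against WT the glycolysis list, Pgk1 included, had 9 of 18 members higher and 3 lower. Whether the excess in C185G has the same source as that in C185Gneo was not tested. Whether the counts may include transcripts of a selection cassette with a Pgk1 promoter stays open, since the drop in C185G belongs to the pattern that prompted this hypothesis and does not test it. In allele names neo usually marks a neomycin selection cassette, but the labels say no more of one, and reads were not analysed here.

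Single libraries stood far from the other 3 of their group in 22 of 561 groups of values tested, where chance gives about 1 in 20 groups, or 28. The number given is the gap to the nearest library over the range of the group, and levels are on the deposited log2 scale. The total count of WT 4 was 16328539 against 18156882 to 18234353 (0.963). In WT, Gsta1 was high in replicate 3 (9.23 against 9.04 to 9.06; 0.912), Psmb4 high in replicate 3 (13.37 against 13.31 to 13.32; 0.854), Taldo1 low in replicate 1 (13.74 against 13.81; 0.963), and in replicate 4 Klf6 was high (0.843), Lpl low (12.38 against 12.63 to 12.66; 0.878) and Cct3 high (0.835).

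In C185Gneo 1, Vegfa was low (15.06 against 15.40 to 15.43; 0.935), Ctsz high (0.86), Bub1 high (10.76 against 10.44 to 10.49; 0.832) and Cbr2 low (18.27 against 18.51 to 18.54; 0.865). Edem3 was low in C185Gneo 2 (0.851). In C185Gneo 3, Proz (11.45 against 11.92 to 12.02; 0.835), Akr1b8 (0.91) and the mean of the cholesterol synthesis list (13.05 against 13.24 to 13.27; 0.851) were low. In C185Gneo 4, Gsta1 was high (9.90 against 8.58 to 8.73; 0.882) and Ly6i low (8.31 against 8.95 to 9.01; 0.915). In C185G 1, Oas3 (6.40 against 7.50 to 7.54; 0.968), Plac8 (8.58 against 9.26 to 9.30; 0.947), Ager (15.94 against 16.08 to 16.09; 0.915) and Ssr3 (14.30 against 14.52 to 14.55; 0.905) were low, and in C185G 3 Btg2 was low (0.933).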

How the results depend on the processing

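Library totals, median-of-ratios scaling and voom weights were chosen only after the data were seen; the other alternatives were fixed before. No called gene, test of a called list or Sftpc value named in the text turned its direction in any of these alternatives. Counts for C185G against WT, C185G against C185Gneo and C185Gneo against WT were 8702, 9117 and 54 genes without the mean-variance trend and 9241, 9550 and 162 with library quality weights; the cause of the moves in C185Gneo against WT was not tested. Quantile normalization gave 8888, 9283 and 78 genes, a mean of at least 5 CPM 7177, 7464 and 63, only the 8 libraries compared 8669, 8776 and 87 (64 of the last shared with the fit of all 12), library totals 8950, 9360 and 86, median-of-ratios 8874, 9300 and 85, and voom 8791, 9310 and 95. With each library left out in turn the counts ran from 7932 to 9277, from 8414 to 9641 and from 40 (without WT 1) to 81 (without WT 2), and those against both controls from 7069 to 8361. The limma count in C185Gneo against WT was 45 without WT 3, 51 without WT 4, and 43, 42 and 44 without C185Gneo 1, 2 and 3. Sftpc ran from -1.44 to -1.34, from 1.60 to 1.77 and from -3.17 to -3.01.

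Camera with an estimated correlation called 0, 0 and 0 of 32 lists in place of 15, 19 and 16, while fry called 21, 26 and 0; limma gave 1534 genes with an unadjusted p under 0.05 in the comparison with 0 by fry. Leaving out libraries gave 14 to 19, 19 to 21 and 10 (without C185Gneo 1) to 20 (without WT 2) lists. With the replicate number as a block the counts were 8670, 9112 and 63 genes, 7752 against both controls, and 15, 19 and 16 lists. The labels do not say what the number marks: same-number libraries correlated at -0.13 to 0.18 in their deviations from the group means, 2 of 12 pairs over 0.1, and 4 libraries correlated best with their own number. Over all named genes the other settings left 4697 outcomes on the same side of the threshold, with 64 weaker and 30 stronger; the left-out libraries gave 4148, 126 and 22. For lists these numbers were 583, 69 and 20, and 721, 19 and 28. Tests for counts alone and another pseudocount were not run, since the unit is log2; the fit reported already has no filter, and the mean of at least 5 CPM is the filter set against it. Depth limits genes such as Mt3, with 1 to 9 counts per WT library.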

Other observations

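Gene families were formed by symbol, and the tests in this part were all chosen only after the data were seen. Families can share genes with the fixed lists. The tRNA synthetase genes Aars and Nars, for example, also belong to the PERK-ATF4 list, so the synthetase result is not independent of it. All 20 cytosolic aminoacyl-tRNA synthetase genes, whose products charge tRNAs for translation, rose in C185G against WT (median 0.59, camera adjusted p = 4.72e-10, and adjusted p = 0.0435 with an estimated correlation) and against C185Gneo (median 0.64, adjusted p = 4.95e-10, and adjusted p = 0.0477 with an estimated correlation). All 8 subunit genes of the CCT chaperonin, which folds actin and tubulin, rose against both (medians 0.72 and 0.76, adjusted p = 0.056 and 0.0753 with an estimated correlation), Cct3 by 1.07 against WT. Of 11 cornified envelope and S100 genes 9 rose and 0 fell against each control (medians 1.70 and 1.93, adjusted p = 0.056 and 0.0753 with an estimated correlation), S100a14 by 2.65 against WT. Aldo-keto reductase genes rose in 8 of 11 cases and fell in 1 against each control (medians 1.27 and 1.18, adjusted p = 0.126 and 0.143 with an estimated correlation).

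Of 74 mitochondrial ribosomal protein genes 53 rose and 2 fell against WT (median 0.41, adjusted p = 0.056 with an estimated correlation), with Mrpl11 at 1.22, and of 84 cytosolic ones 53 rose and 2 fell (median 0.23, adjusted p = 0.442 with an estimated correlation). Of 7 histone genes measured 5 fell and 0 rose against WT (median -1.29, adjusted p = 0.171 with an estimated correlation), with Hist2h2be at -2.33. Immunoglobulin genes, which share sequence, rose in 44 of 121 cases and fell in 1 against C185Gneo (median 1.65, adjusted p = 0.177 with an estimated correlation), and in 12 and 3 against WT (median 0.43, camera adjusted p = 0.197). In C185Gneo against WT 3 fell and 1 rose (median -1.27, camera adjusted p = 9.5e-17, and adjusted p = 0.0991 with an estimated correlation). Under quantile, library-total and median-of-ratios scaling, 0 of 17 family medians turned sign against WT, 1 against C185Gneo (keratins) and 1 in C185Gneo against WT (histones).

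On chromosome 14, which carries Sftpc, 6 of 535 genes were called in C185Gneo against WT (1.12%), against 81 of 15482 elsewhere (0.523%; Fisher's exact test, two-sided p = 0.0708). The 6 include Sftpc itself. Reep4, 21.2 kb from Sftpc, was lower (-0.33, adjusted p = 0.0484), and also in C185G against WT (-0.37, adjusted p = 0.000348). In C185Gneo against WT it kept its call without C185Gneo 1 (0.0244) and lost it without WT 1, 2, 3 or 4 (0.156, 0.109, 0.153 and 0.0628) or C185Gneo 2, 3 or 4 (0.134, 0.153 and 0.103). It also lost it without the mean-variance trend, with quantile, library-total or median-of-ratios scaling, with only the 8 libraries, with the replicate block and with voom weights (0.0506 to 0.0973), and kept it with library quality weights and with a minimum mean of 5 CPM. Scara5 (1.18, adjusted p = 0.00043) lies 4760 kb from Sftpc and Lrmda (-2.05, adjusted p = 4.91e-05) 47500 kb. Lrmda was also lower in C185G than in WT (-2.62, adjusted p = 4.54e-08).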
